A study of Mus musculus with 4 samples.

How the data were processed

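RNA-seq libraries were made from live tdTomato-positive cells sorted from papain-digested forebrains (30 min) of postnatal day 4 mice, 2 libraries of the PdgfraCreER;AI14 genotype (control) and 2 that also carried MN1:BEND2 (fusion). Full-length cDNA was amplified with a single-cell kit and sequenced on an MGISEQ-2000 with 100 bp paired-end reads, per the labels' protocols. PCR copies of 1 molecule are not marked in such libraries. The labels do not state a strand-specific kit. Groups were taken from the genotype in the sample titles and columns were matched to samples by group and replicate number. The protocols speak of forebrains from individual mice, but no label says that the 2 libraries of a group came from separate mice, so p-values measure the spread between these libraries, which may be technical.

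The authors deposited 1 table of TPM with 54348 rows, 1 for each gene, in which each library sums to the same total. Trimmomatic 0.39 and Salmon 1.8.0 and the builds GRCm38 and mm10 are named in the submitters' processing notes. The annotation release, the index, and how transcript values were summed to genes are not given in the sources used here. TPM divides by transcript length and by the library total, so genes that take a larger share lower all others, and it keeps no depth. Depth per library is therefore unknown, no counting interval or floor is given, and an exact 0 is described only as listed at 0. Coordinates, GC content and transcript length came from GENCODE release M21 (GRCm38), matched by Ensembl gene identifier. Of the tested genes, 12862 of 12871 had a GC content and a length. Where rows share a symbol, which holds for 105 rows, the symbol names the row of highest mean.

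Genes with at least 1 TPM in at least 2 of the 4 libraries were tested. Values were log2(TPM + 1), so a change is on that scale and understates the change of low genes. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a mean-variance trend, 2-sided), with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The prior had 3.25 degrees of freedom beside 2 residual ones. Gene lists were tested with camera at a preset correlation of 0.01, over lists with at least 5 tested members and without the sex-linked list, and members were also counted with p adjusted over the list alone. The design, the alternatives, the 40 lists and the rule for named genes were written before the data were examined. The rule took Mn1, Bend2 and Pdgfra first. It then took, among genes past the threshold with both fusion libraries on the same side of both control libraries, a mean of at least 5 TPM and a symbol that is not a predicted or pseudogene model, the 12 largest rises and 12 largest falls. For lists that passed and for cell type lists it took up to 4 past members with the largest change, or up to 3 with the highest mean where none passed. Some genes that the rule takes are not reported here. Members of other lists, Isg15, P2ry12, Sox1 and the genes said to turn with rescaling were chosen after their values were seen.

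The fit was tested on simulated data of 12871 genes with 2 libraries a group, drawn with the control means and variances from the fitted prior. With 200 genes changed, 42% of those lowered and 28% of those raised by 4 log2 units were called, and 0% of those changed by 2. With 6315 other genes also lowered by 2, as a case nearer to these data, 96% and 100% of genes changed by 4 were called, and 64% and 68% of those lowered or raised by 2, and 2.41% of calls were of unchanged genes. A list of 20 genes raised by 2 passed in both cases (adjusted p = 4.53e-26 and 8.92e-22). In the second case an unchanged list of 20 genes passed too (adjusted p = 0.000135), where the other genes include the lowered ones. The simulation gave each gene 1 variance in both groups, with noise independent between genes. The real fusion libraries were less alike than the control libraries (Pearson correlation 0.894 against 0.973). The percentages of genes called may therefore not hold for the real data.

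Alternatives were a pseudocount of 0.1 or 5, no filter on low values (every gene above 0 in a library), a mean of at least 5 TPM, median ratio scaling over 10965 genes above 0 in every library, quantile normalization, TPM renormalized without mitochondrially encoded and ribosomal protein genes, limma without the trend or with robust hyperparameters, a replicate block, each library left out, camera with an estimated correlation, fry, and a change of at least 1. Chosen after seeing the data were a correction for GC content and length (a loess of each library's deviations, span 0.3) and TPM renormalized without mitochondrially encoded genes and 3 gene models that share their reads. The correction subtracts the whole fit, so it also takes out most of the shift common to the genes of a library. Groups of 2 are too small for outlier tests and for other splits of the libraries.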

Results

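The data were RNA-seq profiles of cells sorted from the forebrains of mouse pups killed at postnatal day 4. Mice carried PdgfraCreER, a tamoxifen-activated recombinase expressed from the Pdgfra gene, and AI14, a reporter that makes the red protein tdTomato after recombination. Pdgfra encodes the alpha receptor for platelet-derived growth factor, a marker of oligodendrocyte precursor cells that is also made by some fibroblasts. In the fusion group the mice also carried MN1:BEND2, the fusion gene of astroblastoma, a brain tumour. Tamoxifen was injected on postnatal days 0 and 1, and live tdTomato-positive cells were collected by fluorescence-activated sorting. There were 2 control and 2 fusion libraries. The comparison asks what the Pdgfra lineage expressed at postnatal day 4 with the fusion gene and without it.

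Values were given as TPM, the share of transcripts, which sum to the same total in each library, so the read depth of the libraries is unknown. The libraries of the groups stood apart in quality measures. Mitochondrially encoded genes took 10.1% and 7.30% of TPM in control replicates 1 and 2, and 48.7% and 26.2% in fusion replicates 1 and 2. The gene mt-Atp8, for a subunit of ATP synthase, alone took 22.9% and 12% of TPM in the fusion libraries. In the control libraries it took 3.59% and 2.34%. It overlaps mt-Atp6 on the same strand, and how reads common to both were divided is uncertain. Genes at 1 TPM or more numbered 12772 and 13219 in the control libraries and 9050 and 10017 in the fusion libraries. The 10 genes of highest TPM in each library held 14.2% and 11.7% in the control libraries and 51.5% and 30.7% in the fusion libraries. Across the 12871 genes tested, log2(TPM + 1) values had a Pearson correlation of 0.973 between the control libraries and 0.894 between the fusion libraries, and of 0.676 to 0.735 between groups; genes are not independent replicates.

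**Figure D1:**
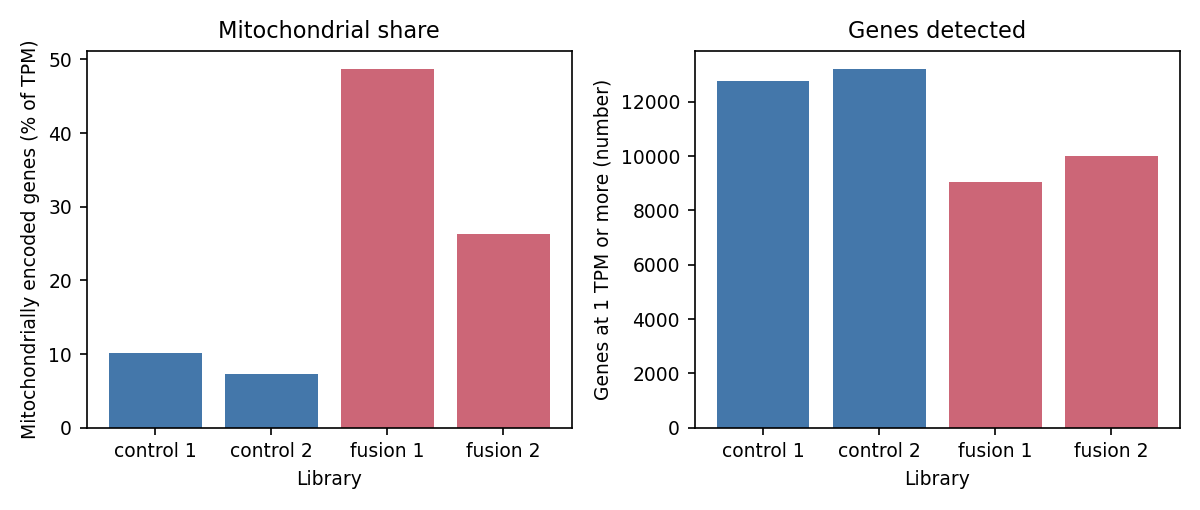
The left panel shows the percentage of TPM in mitochondrially encoded genes and the right panel the number of genes at 1 TPM or more, 1 bar for each library (blue, control; red, fusion). The fusion libraries held 48.7% and 26.2% mitochondrial TPM, against 10.1% and 7.30% in the control libraries, and fewer genes.

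The genes named by the construct were read first, as a check of the labels. Bend2 was listed at 0 in both control libraries and at 3.82 and 8.72 TPM in the fusion libraries (adjusted p = 0.00640, limma). Its row carries a symbol in place of a gene identifier, and which sequence it stands for is not given in the sources used here. Mouse Mn1 (ENSMUSG00000070576.4, chromosome 5, 111417362 to 111457033, GRCm38) had 14.7 ± 4.41 TPM in the control and 2.90 ± 0.202 TPM in the fusion libraries (SD, n = 2), a log2 change of -1.98 ± 0.44 (SE, adjusted p = 0.0158). Pdgfra (ENSMUSG00000029231.15, chromosome 5, 75152292 to 75198215) had 383 ± 65.5 and 158 ± 48.3 TPM (SD, n = 2), a log2 change of -1.30 ± 0.38 (SE, adjusted p = 0.0358). Relative to the median change of all tested genes, described next, Mn1 lay at -0.58 and Pdgfra at 0.11. With libraries rescaled to a median ratio of 1, Mn1 changed by -0.47 (adjusted p = 0.449) and Pdgfra by 0.46, in the other direction (adjusted p = 0.186). Over all settings tried, the change ranged from -2.27 to -0.45 for Mn1 and from -1.62 to 0.46 for Pdgfra. None of Mn1, Bend2 and Pdgfra passed the threshold without control replicate 1 or without control replicate 2.

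Sex-linked genes parted the groups. Eif2s3y, a translation factor gene on the Y chromosome, had 121 and 122 TPM in the control libraries and was listed at 0 in both fusion libraries. Ddx3y, Uty and Kdm5d, also on the Y chromosome, had 18.8 and 19.8, 10.7 and 10.7, and 5.65 and 4.62 TPM in the control libraries, and at most 0.273 TPM in a fusion library. Tsix, the antisense partner of the X-inactivation RNA Xist, had 0 and 0.0239 TPM in the control and 72.1 and 18.8 TPM in the fusion libraries. Xist was at 0.510 TPM or less in each library. The 2 overlap on opposite strands, and reads without strand cannot be told apart between them. Sex and genotype were therefore fully confounded in these 4 libraries, for every result that follows.

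Most genes that changed were lower in the fusion libraries. Of 12871 genes tested, 637 rose and 6606 fell at an adjusted p under 0.05 (limma, Benjamini-Hochberg), so that 91.2% of the calls were lower; 5628 genes did not pass. The median log2 change over all tested genes was -1.41. With libraries rescaled to a median ratio of 1, 1843 genes were higher and 2392 lower, 56.5% of calls, and the median change was -0.15; 634 of the genes that rose and 2392 of those that fell were called in the same direction in both. With quantile-normalized values the split was 1948 to 1955. Changes relative to the median of -1.41 are therefore given beside the changes themselves. The 2 fusion libraries lay above both control libraries for 1316 genes and below both for 9147, 81.3% of genes together. For 1 gene with interchangeable libraries chance gives 33.3%. A shift common to a library moves many genes together, so these genes are not independent cases. After rescaling these counts were 4024 and 4991, or 70.0%. Without control replicate 1 the counts were 15 and 1105, and without control replicate 2 they were 14 and 1025, with the lone control library assumed to vary as the fusion libraries did. Without fusion replicate 1, the library with the highest mitochondrial share, 1084 genes were higher and 6679 lower.

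The largest rise was of Ccl12. Ccl12 (ENSMUSG00000035352.3), a monocyte-attracting chemokine, went from 0.0503 ± 0.0711 to 862 ± 765 TPM (SD, n = 2; log2 change 9.32 ± 0.74, SE, adjusted p = 0.00367, limma). Its neighbours on chromosome 11, Ccl2 (82035571 to 82037453) and Ccl7 (82045712 to 82047525), went from 0.416 ± 0.589 to 456 ± 31.5 TPM and from 0.509 ± 0.720 to 298 ± 91.2 TPM. These 3 chemokines are related in sequence, and how reads common to them were divided is uncertain. Ccl5 went from 1.81 ± 0.589 to 300 ± 3.62 TPM, and Ccl4 was listed at 0 in both control libraries and at 125 and 93.4 TPM in the fusion libraries. Cxcl10, an interferon-induced chemokine, was listed at 0 in both control libraries and at 131 and 291 TPM in the fusion libraries. Ifi27l2a and Xaf1, also induced by interferon, rose from 2.95 ± 3.46 to 623 ± 288 TPM and from 1.63 ± 0.736 to 242 ± 203 TPM. The other genes of the largest 12 rises were Mgp, for a matrix protein that inhibits calcification (0.671 ± 0.949 to 541 ± 250 TPM), Cd52, for a surface protein of white blood cells (0.123 ± 0.0222 to 111 ± 63.5 TPM), Plac8 and Sct. Plac8 was listed at 0 in both control libraries and at 266 and 239 TPM in the fusion libraries; Sct, for the hormone secretin, at 0 and at 59.5 and 118 TPM. Log2 changes of the 12 ran from 6.25 to 9.32, and all 12 passed with rescaled or quantile-normalized values. Tyrobp, a myeloid marker given below, had 16.6 and 7.66 TPM in the control and 105 and 116 TPM in the fusion libraries. Without control replicate 1, 6 of the 12 passed, and without control replicate 2 also 6.

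The largest fall was of Eif2s3y, given above. Nnat (ENSMUSG00000067786.16, chromosome 2, 157560078 to 157562522), an imprinted gene, went from 2818 ± 283 to 30.8 ± 18.3 TPM (SD, n = 2; log2 change -6.59 ± 0.50, SE, adjusted p = 0.00367, limma). It overlaps Blcap on the other strand. Ap2m1, for a subunit of a clathrin adaptor, went from 1482 ± 47.6 to 15.1 ± 0.304 TPM. Eno1, for the glycolytic enzyme enolase, went from 1070 ± 221 to 10.4 ± 4.61 TPM. Its near copy Eno1b had 5.11 and 4.58 TPM in the control and 0.865 and 1.09 TPM in the fusion libraries. The log2 change of Eno1b was -1.56, or -0.37 after rescaling and 0.62 with the GC and length correction. How reads common to Eno1 and Eno1b were divided is uncertain. Pllp, for the myelin protein plasmolipin, went from 667 ± 39.6 to 8.11 ± 0.437 TPM, and Gpx3, for a glutathione peroxidase, from 359 ± 59.6 to 3.53 ± 0.0291 TPM. Tubg1 and Aurka, for gamma-tubulin and a mitotic kinase, went from 95.1 ± 17.4 to 0.203 ± 0.192 TPM and from 80.8 ± 6.49 to 0.103 ± 0.146 TPM. Scamp4 and Pgpep1 went from 130 ± 24.0 to 0.703 ± 0.112 TPM and from 168 ± 25.7 to 1.34 ± 0.254 TPM. The log2 changes of the genes named here ran from -6.93 to -6.17, which is -5.53 to -4.77 relative to the median, and all 12 genes with the largest falls passed with rescaled or quantile-normalized values. Without control replicate 1, 6 of the 12 passed, and without control replicate 2, 5.

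**Figure D2:**
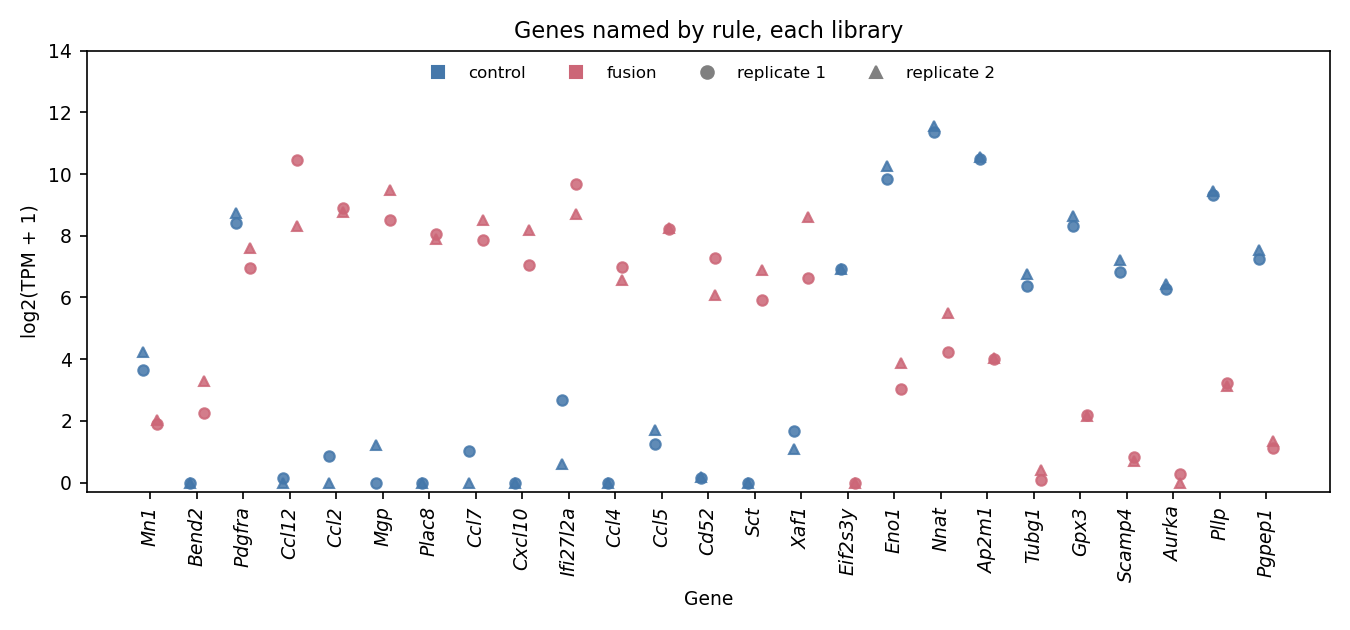
Each point is 1 library, with log2(TPM + 1) on the vertical axis and genes named by rule on the horizontal axis (blue, control; red, fusion; circle, replicate 1; triangle, replicate 2). The fusion libraries lay above both control libraries for Bend2 and below both for Mn1 and Pdgfra. The 12 largest rises, from Ccl12 to Xaf1, and the falls shown, from Eif2s3y to Pgpep1, were taken only from genes whose groups do not overlap.

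Of 40 gene lists fixed before the data were examined, 33 had at least 5 tested members and 10 passed the list test (camera, preset correlation, Benjamini-Hochberg), 7 upward and 3 downward. The test compares a list with the other genes, most of which were lower, so an upward call does not require that members rose. None of the 10 held with an estimated correlation, where the smallest adjusted p was 0.598 and the smallest unadjusted p was 0.0463. That setting rests on the 2 residual degrees of freedom, so hardly any list could pass it. The ependymal list had an estimated correlation of -0.132, below the preset 0.01, yet its unadjusted p went from 0.00242 to 0.0898 (camera). Not passing with an estimated correlation therefore says little about a list. By fry, which tests a list alone, 16 passed, among them the 3 downward lists and 1 of the 7 upward lists, interferon response genes.

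Interferon response genes were the list furthest above the other genes. Of 19 tested members, 15 rose, none fell and 4 did not pass, over all genes and adjusted over the list alone (camera adjusted p = 6.56e-22; adjusted p = 0.598 with an estimated correlation). The median log2 change was 2.45, or 3.86 relative to all genes, and 18 of 19 were higher after rescaling. Ifitm3, which blocks virus entry, rose from 20.3 ± 7.24 to 1283 ± 210 TPM, and Oasl2 from 0.462 ± 0.653 to 46.6 ± 15.1 TPM (SD, n = 2). Ifit1 was listed at 0 in both control libraries and at 26.0 and 79.5 TPM in the fusion libraries. Isg15 was at 0.524 TPM or less in each library and was not tested. Antigen presentation genes passed too, with 3 of 9 tested members higher and 6 not past the threshold, over all genes and adjusted over the list alone (adjusted p = 8.26e-06; 0.598 with an estimated correlation). After rescaling, 6 were higher and 3 did not pass. B2m, the shared light chain of class I molecules and a member of both lists, rose from 415 ± 4.78 to 4669 ± 427 TPM, and H2-K1 from 26.0 ± 0.971 to 339 ± 93.7 TPM. H2-T23 rose from 8.46 ± 0.947 to 48.1 ± 4.71 TPM. H2 genes are related in sequence, so their separate values are uncertain. The mitochondrial list, given below, moved the same way in the same libraries. The microglia list, also given below, passed upward too, with 3 of 12 tested members higher and 2 lower.

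Collagen and matrix genes passed upward, with members on both sides. Of 25 tested, 5 rose, 5 fell and 15 did not pass; adjusted over the list alone, 5 rose and 4 fell (adjusted p = 8.28e-08; 0.598 with an estimated correlation; median relative to all genes 2.43). After rescaling, 16 were higher, 1 was lower and 8 did not pass. Fn1, for fibronectin, rose from 1.97 ± 0.0565 to 71.4 ± 8.11 TPM, and Col2a1 from 0.0974 ± 0.138 to 8.89 ± 3.26 TPM. Ncan and Bcan, for proteoglycans of the brain matrix, fell from 159 ± 1.54 to 11.9 ± 1.84 TPM and from 97.0 ± 17.5 to 15.8 ± 11.3 TPM (SD, n = 2). Meningeal and perivascular fibroblast markers had 3 members that rose, 1 that fell and 12 that did not pass among 16 tested, over all genes and adjusted over the list alone (adjusted p = 4.57e-06; 0.598 with an estimated correlation). After rescaling, 8 were higher, none lower and 8 did not pass. Mgp, given above, Col1a1 (6.53 ± 3.88 to 38.8 ± 18.2 TPM) and Foxc1 (0.316 ± 0.215 to 5.70 ± 1.74 TPM) rose, and Pdgfrl fell from 7.26 ± 4.10 to 0.343 ± 0.484 TPM. Pial membranes had been removed before the tissue was dissociated, per the labels' protocols.

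Of 12 tested microglia and macrophage markers, 3 rose, 2 fell and 7 did not pass, over all genes and adjusted over the list alone (camera adjusted p = 0.00124, or 0.598 with an estimated correlation). Among all 12871 tested genes, 637 rose and 6606 fell. The median log2 change of the list was 0.22, or 1.62 relative to all genes. Tyrobp, Aif1 and Ctss rose from 12.1 ± 6.29 to 110 ± 7.78, from 2.37 ± 2.32 to 24.3 ± 16.3 and from 4.89 ± 2.15 to 22.1 ± 8.80 TPM (SD, n = 2). P2ry12, which fell, had 1.81 and 1.03 TPM in the control libraries and was listed at 0 in both fusion libraries. After rescaling, 3 members were higher and 1 was lower. The list did not pass after rescaling (adjusted p = 0.0564) or without control replicate 2, and its adjusted p with the preset correlation ranged from 0.000105 to 0.0714 over the settings. Ependymal and motile cilia markers had 6 tested members, of which 1 rose, 1 fell and 4 did not pass, over all genes and adjusted over the list alone (adjusted p = 0.00999; 0.598 with an estimated correlation). Ccno, needed to make the basal bodies of motile cilia, rose from 0.0993 ± 0.140 to 2.68 ± 0.299 TPM. Rsph1, for a part of the ciliary axoneme, had 1.93 and 1.90 TPM in the control libraries and was listed at 0 in the fusion libraries, though its change turned to 0.01 with the GC and length correction. After rescaling, 2 members were higher and 1 was lower. That list did not pass with no filter, after rescaling (adjusted p = 0.157), with quantile-normalized values, without control replicate 2 or by fry (adjusted p = 0.333), and with a mean of at least 5 TPM it had too few members to test. Mitochondrially encoded genes, a quality list, had 5 of 15 members higher and 10 not past the threshold, over all genes and adjusted over the list alone (adjusted p = 2.69e-11; 0.598 with an estimated correlation), and 14 higher after rescaling. mt-Rnr1 and mt-Nd2 rose by log2 changes of 2.27 and 1.91, and mt-Atp6 and mt-Atp8 each rose by 2.52. The last 2 ranked highest in every library, so quantile normalization sets their change to 0 by construction.

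Proliferation genes were the downward list with the smallest p. Of 20 tested, 19 fell and 1 did not pass, and 20 fell adjusted over the list alone (adjusted p = 0.00344; 0.598 with an estimated correlation). The median log2 change was -2.95, or -1.55 relative to all genes, and after rescaling 7 members were lower and 13 did not pass. Besides Aurka, the mitotic genes Ccnb1, Kif20a and Plk1 fell from 319 ± 19.9 to 15.6 ± 9.48, from 29.9 ± 6.29 to 0.553 ± 0.0792 and from 32.1 ± 16.6 to 0.937 ± 1.04 TPM (SD, n = 2). Top2a and Ccna2 turned upward after rescaling, by 0.35 and 0.22, without passing. Cholesterol synthesis genes had 17 of 21 members lower and 4 not past the threshold, or 20 lower adjusted over the list alone (adjusted p = 0.0143; 0.598 with an estimated correlation; median relative to all genes -1.71), and 11 lower after rescaling. Mvd, Fdft1, Mvk and Fdps, for enzymes of the pathway, fell from 54.5 ± 22.3 to 1.72 ± 0.323, from 128 ± 6.87 to 7.80 ± 4.80, from 58.7 ± 23.8 to 3.33 ± 3.25 and from 448 ± 15.7 to 30.9 ± 18.8 TPM. Unfolded protein and amino acid stress genes had 12 of 15 members lower and 3 not past the threshold, or 13 lower adjusted over the list alone (adjusted p = 0.0219; 0.598 with an estimated correlation), and 10 lower after rescaling. Pdia4, Phgdh and Herpud1 fell from 88.2 ± 24.9 to 2.35 ± 0.604, from 127 ± 57.6 to 4.16 ± 0.533 and from 66.3 ± 1.8 to 2.28 ± 2.30 TPM, and Asns, for asparagine synthetase, from 138 ± 23.2 to 4.99 ± 0.00783 TPM. These 3 lists did not pass without control replicate 1 or without control replicate 2, and the third also not with a mean of at least 5 TPM; over the settings their adjusted p with the preset correlation rose to at most 0.0612, 0.0890 and 0.0741. The lower number of genes detected in the fusion libraries moved with these falls.

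**Figure D3:**
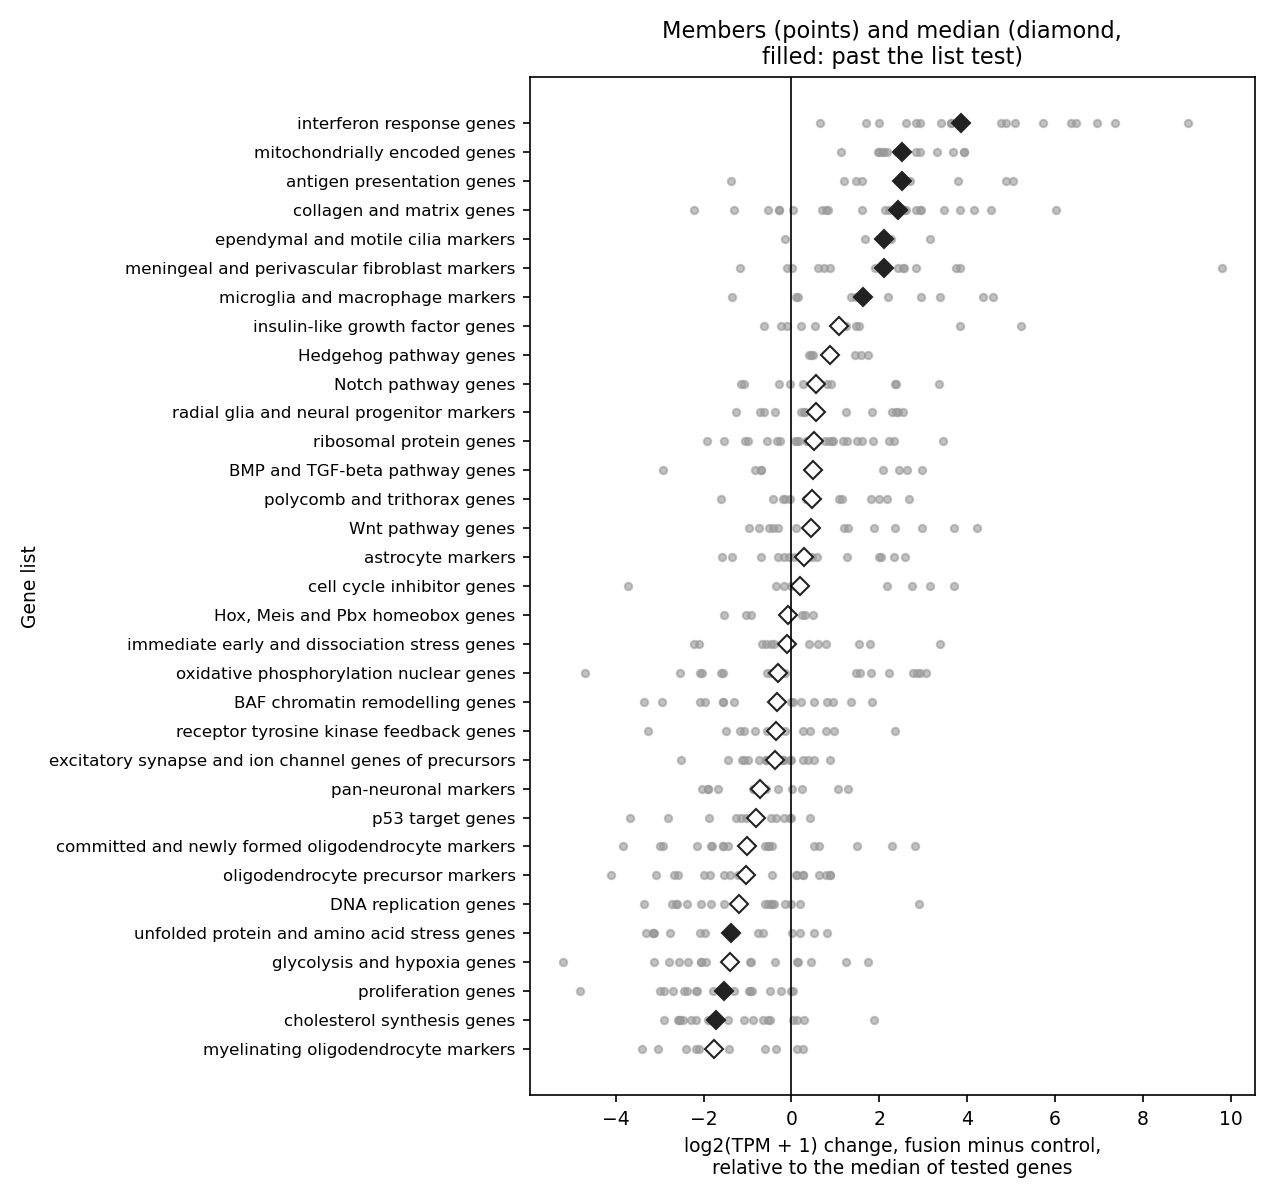
Each row is a gene list with at least 5 tested members, and the horizontal axis is the log2(TPM + 1) change, fusion minus control, relative to the median of all tested genes. Grey points are members and diamonds are list medians, filled where the list passed with the preset correlation. Interferon response genes had the highest median, 3.86, and members of most lists lay on both sides of 0.

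Oligodendrocyte lineage markers, those of the sorted cells, did not pass as lists in the main setting. The precursor and myelinating lists passed downward with a pseudocount of 0.1 or 5, with no filter, with the GC and length correction and by fry, the myelinating list also with quantile-normalized values, and the newly formed list with no filter and by fry. With an estimated correlation the adjusted p was 0.641 for the precursor list and 0.632 for each of the others. Of 20 precursor markers, 14 fell and 6 did not pass, or 15 fell adjusted over the list alone (adjusted p = 0.0528; median relative to all genes -1.03). Sox6, for a transcription factor of precursors, fell from 346 ± 55.9 to 6.69 ± 2.00 TPM, and Neu4, Rlbp1 and Gpr37l1 fell from 51.4 ± 17.5 to 1.46 ± 1.35, from 356 ± 106 to 19.9 ± 3.37 and from 305 ± 120 to 18.5 ± 8.16 TPM (SD, n = 2). After rescaling, 7 precursor markers were lower, 1 was higher and 12 did not pass. Olig1, Olig2, Ptprz1, Vcan, Xylt1, Tnr and Pcdh15 changed sign with it, as Pdgfra did. Of 18 markers of committed and newly formed oligodendrocytes, 13 fell and 1 rose, also adjusted over the list alone (adjusted p = 0.183), and 7 were lower and 2 higher after rescaling. Sirt2, Lims2, Bmp4 and Itpr2 fell from 1239 ± 84.4 to 32.2 ± 9.44, from 731 ± 8.29 to 33.7 ± 2.24, from 214 ± 3.84 to 10.8 ± 7.06 and from 26.2 ± 13.8 to 1.16 ± 0.0960 TPM. Lims2 overlaps Gpr17, another marker of this list, on the other strand. Where they overlap, reads without strand cannot be told apart between them. Of 10 tested markers of myelinating oligodendrocytes, 8 fell, or 10 adjusted over the list alone (adjusted p = 0.0526), and 5 were lower after rescaling. Cnp and Mbp, for myelin proteins, fell from 559 ± 216 to 18.2 ± 1.45 and from 776 ± 349 to 60.9 ± 0.689 TPM, and Gjb1 from 23 ± 8.84 to 0.0762 ± 0.108 TPM.

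Markers of other cell types moved in both directions, and counts turned with rescaling. After it, 4 astrocyte markers were higher and 2 lower, 6 radial glia and progenitor markers were higher and none lower, and 2 pan-neuronal markers were lower, or none adjusted over the list alone. Of 16 astrocyte markers tested, 7 fell and 9 did not pass, or 6 fell adjusted over the list alone (adjusted p = 0.591), with Aldoc at 107 ± 10.1 and 12.8 ± 3.14 TPM and Acsbg1 at 6.89 ± 3.20 and 0.128 ± 0.181 TPM. F3 and S100b, also astrocyte markers, fell from 61.9 ± 3.05 to 14.1 ± 4.86 and from 211 ± 12.5 to 63.7 ± 11.3 TPM. After rescaling F3 changed by -0.39, and S100b turned to 0.03. Of 15 radial glia and progenitor markers, 6 fell and 1 rose, also adjusted over the list alone (adjusted p = 0.137). Slc1a3, Ednrb and Emx2 fell from 125 ± 22.6 to 21.2 ± 14.8, from 438 ± 13.5 to 109 ± 33.9 and from 1.44 ± 0.320 to 0.0722 ± 0.102 TPM, though Emx2 turned to 0.04 with quantile-normalized values and to 0.77 with the GC and length correction, and Sox1 rose from 0.0297 ± 0.0211 to 1.26 ± 0.198 TPM. Of 13 pan-neuronal markers, 10 fell, also adjusted over the list alone (adjusted p = 0.183), with Elavl4 at 80.9 ± 8.51 and 7.74 ± 6.40 TPM and Stmn3 at 602 ± 89.5 and 70.5 ± 53.1 TPM. Tubb3 and Snap25 fell from 21.8 ± 0.295 to 1.35 ± 0.662 and from 134 ± 2.46 to 16.7 ± 11.2 TPM. The remaining cell type lists had fewer than 5 tested members and no list test. Eomes, the single tested member of the excitatory neuron list, rose from 0.0305 ± 0.0431 to 4.07 ± 0.305 TPM. All 12 members of that list together went down, from a mean sum of 8.37 TPM in the control to 5.43 TPM in the fusion libraries. Of 4 inhibitory neuron markers, Npy rose from 28.6 ± 3.44 to 124 ± 76.5 TPM, but none rose adjusted over the list alone. Of 3 endothelial markers, Ramp2 fell from 87.8 ± 11.4 to 17.7 ± 2.56 TPM and Cdh5 rose from 0.202 ± 0.0704 to 1.12 ± 0.0128 TPM. Of 4 pericyte and smooth muscle markers, Cspg4, also a precursor marker, fell from 57.0 ± 16.1 to 8.30 ± 1.14 TPM. After rescaling, higher and lower members numbered 2 and 0 for inhibitory neuron, 1 and 0 for endothelial and 1 and 1 for choroid plexus markers. No pericyte and smooth muscle marker passed after it. Ramp2 then changed by -0.52 and Cspg4 by -0.94. Of 3 choroid plexus markers, Ttr rose from 0.128 ± 0.180 to 61.2 ± 64.8 TPM, Sostdc1, at 11.9 and 12.8 TPM in the control libraries, was listed at 0 in the fusion libraries, and Otx2 fell from 1.95 ± 0.607 to 0.189 ± 0.268 TPM, though upward by 0.40 with the GC and length correction. Neither of 2 red blood cell genes passed, with Hba-a2 at 5.32 ± 3.33 and 2.45 ± 1.93 TPM and Hbb-bs at 1.23 ± 1.74 and 2.34 ± 3.31 TPM.

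The other pathway lists did not pass the list test in the main setting; those that passed in another are named in the closing section. Counts after rescaling are given last. Downward counts before it were highest for DNA replication genes (16 of 20 fell and 1 rose; 18 fell adjusted over the list alone; adjusted p = 0.0528), excitatory synapse and ion channel genes (15 of 21; 16 adjusted over the list alone; adjusted p = 0.106), BAF chromatin remodelling genes (13 of 18; 13 adjusted over the list alone; adjusted p = 0.212) and p53 target genes (12 of 14; 13 adjusted over the list alone; adjusted p = 0.0620). Glycolysis and hypoxia genes tied with p53 target genes, as 12 of 17 fell, also adjusted over the list alone (adjusted p = 0.0763). Of 12 receptor tyrosine kinase feedback genes 7 fell, also adjusted over the list alone (adjusted p = 0.365). Nuclear genes of oxidative phosphorylation went both ways, with 10 of 19 lower and 3 higher, or 11 and 3 adjusted over the list alone (adjusted p = 0.267). Uqcrc1 fell from 762 ± 72.7 to 12.6 ± 11.2 TPM, while Ndufa4 rose from 1933 ± 164 to 6044 ± 212 TPM. Ribosomal protein genes, a quality list, had 9 of 25 members lower and 1 higher, or 6 and 1 adjusted over the list alone (adjusted p = 0.234), with Rpl4 at 715 ± 19.1 and 71.7 ± 20.2 TPM and Rps27 higher. Of 12 insulin-like growth factor genes, H19 (0.375 ± 0.228 to 18.5 ± 3.30 TPM) and Igf2 (14.6 ± 12.1 to 73.5 ± 33.7 TPM) rose and 3 fell, also adjusted over the list alone (adjusted p = 0.0585). In the cell cycle inhibitor list, Cdkn1c and Gadd45b rose and 3 of 11 fell, or 2 fell adjusted over the list alone (adjusted p = 0.113). Among 16 Wnt pathway genes 3 rose and 5 fell (adjusted p = 0.0526), and among 11 BMP and TGF-beta pathway genes 2 rose and 4 fell (adjusted p = 0.0859), in each case also adjusted over the list alone. Of 13 immediate early and dissociation stress genes 6 fell and 1 rose (adjusted p = 0.591), and of 12 Notch pathway genes 5 fell (adjusted p = 0.234), with the same counts adjusted over the list alone. Of 8 tested Hox, Meis and Pbx genes 3 fell, also adjusted over the list alone (adjusted p = 0.452), and of 7 Hedgehog pathway genes none passed either way (adjusted p = 0.138). Of 16 polycomb and trithorax genes 6 fell and 1 rose, or 6 and none adjusted over the list alone (adjusted p = 0.397).

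After rescaling, fewer members of most of these lists were lower. Lower members numbered 6 for DNA replication (1 higher), 3 for synapse and ion channel genes, 5 for BAF genes (1 higher), 4 for p53 targets, 7 for glycolysis and hypoxia (1 higher), 3 for receptor tyrosine kinase feedback and 1 for Hox, Meis and Pbx genes. Ribosomal protein genes turned, with 11 higher and 2 lower, and passed upward (adjusted p = 0.00135, camera; 0.789 with an estimated correlation before rescaling). Nuclear genes of oxidative phosphorylation had 7 higher and 5 lower, Wnt pathway genes 6 and 2, cell cycle inhibitor genes 4 and 1, BMP and TGF-beta pathway genes 3 and 1, and polycomb and trithorax genes 3 and 2. No member was lower among Notch pathway genes (3 higher), insulin-like growth factor genes (3 higher), immediate early and dissociation stress genes (1 higher) or Hedgehog pathway genes (1 higher).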

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

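The correction for GC content and length and the renormalization without mitochondrial genes and their copies were chosen after the data were seen; the other settings were not. The 12 largest rises and the 12 largest falls kept their direction in all settings and passed in all but those without a control library. Causes were not tested except where a setting tests fewer genes or libraries. The number of higher genes (637) was 353 with no filter, 405 with a mean of at least 5 TPM, 1843 with median ratio scaling, 1948 with quantile normalization, 970 without mitochondrial and ribosomal protein genes, 1766 with the GC and length correction and 1004 without mitochondrial genes and their copies. The number of lower genes (6606) was 2392, 1955 and 2117 with median ratio scaling, quantile normalization and the correction. The median log2 change of the tested genes in these settings was -0.15, 0 and -0.07. Leaving out 1 library gave 14 to 1084 higher and 1025 to 7987 lower genes, with fewest calls where a control library was left out. The number of lists past the threshold (10) was 21 with no filter, 18 with the GC and length correction, 16 by fry, 0 with an estimated correlation and 5 to 10 without 1 library.

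Mn1 did not pass with median ratio scaling (-0.47), quantile normalization (-0.45) or the GC and length correction (-1.09), and changed by -2.27 to -1.69 without 1 library. Bend2 changed by 2.27 to 3.28 without 1 library, and did not pass without either control library (2.77). Pdgfra reversed with median ratio scaling (0.46) and did not pass with no filter (-1.30), quantile normalization (-0.20), without mitochondrial and ribosomal protein genes (-0.67), with the GC and length correction (-0.11) or without mitochondrial genes and their copies (-0.69), nor without either control library; without 1 library it changed by -1.62 to -0.98.

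The replicate numbers are not said to pair libraries, and deviations from the group means of control and fusion replicate 1 had a correlation of -0.0398 across genes. With a replicate block, 642 genes were higher, 6978 lower and 14 lists passed (also myelinating, DNA replication, insulin-like growth factor, and glycolysis and hypoxia), and the Pdgfra change of -1.30 did not pass. With an estimated correlation and no block, the adjusted p of these 4 lists was 0.598 for insulin-like growth factor genes and 0.632 for the others.

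Lists past the threshold downward only in other settings were, besides the oligodendrocyte lists, DNA replication (pseudocount 5, no filter, quantile normalization, both renormalizations, GC and length correction, fry), glycolysis and hypoxia (no filter, median ratio, quantile, correction, without mitochondrial genes and their copies, fry), p53 target (pseudocount 5, no filter, quantile, fry), synapse and ion channel (no filter, correction, fry), pan-neuronal and BAF (no filter, fry), and receptor tyrosine kinase feedback, Hox, Meis and Pbx, and polycomb and trithorax genes (fry). Upward these were Wnt (pseudocount 5, no filter, correction), insulin-like growth factor (quantile, correction), BMP and TGF-beta (no filter), radial glia (correction) and ribosomal protein genes (median ratio). Inhibitory neuron markers, too few to test in the main setting, passed with no filter and were not tested with an estimated correlation. No list tested in the main setting passed with an estimated correlation, where the smallest adjusted p was 0.598.

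Some lists that did not pass changed in the direction of the list test, for immediate early and nuclear oxidative phosphorylation genes with a relative median that was below 0 in the main setting too. Relative medians were -0.50 and -0.49 for astrocyte markers and polycomb and trithorax genes with no filter, -0.21 and -0.27 for immediate early genes and BMP and TGF-beta genes with a mean of at least 5 TPM, and -0.25 and -0.0853 for nuclear oxidative phosphorylation and ribosomal protein genes with quantile normalization. Ribosomal protein genes also turned without fusion replicate 2 by the test's direction, with relative medians of 0.35 to 0.77 without 1 library. By fry, which does not compare with other genes, 12 lists turned downward, of which polycomb and trithorax genes passed, with medians of -1.11 (astrocyte), -0.86 (radial glia), -1.51 (immediate early), -1.21 (cell cycle inhibitor), -0.84 (Notch), -0.96 (Wnt), -0.54 (Hedgehog), -0.92 (BMP and TGF-beta), -0.32 (insulin-like growth factor), -1.70 (oxidative phosphorylation), -0.93 (polycomb and trithorax) and -0.89 (ribosomal protein). Depth is unknown, so what it limits cannot be stated.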

Other observations

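Genes in this paragraph were chosen after their values were seen. Several imprinted genes of growth control were higher in the fusion libraries: Plagl1, for a zinc finger protein, had 1.8 and 0.367 TPM in the control and 72.1 and 49.4 TPM in the fusion libraries (log2 change 4.96, adjusted p = 0.00380, limma), and Dlk1 had 0.0184 and 0.499 against 4.97 and 5.08 TPM (2.29, adjusted p = 0.00637). H19, Igf2 and Cdkn1c, given above, were also higher, while Nnat and Meg3 fell, Meg3 from 50.5 and 71.7 to 9.10 and 16.5 TPM (-2.20, adjusted p = 0.0119; -0.51 and not past the threshold after median ratio scaling). Igfbp7, for a secreted protein that binds insulin-like growth factors, had 0.483 and 0.229 against 33.4 and 64.9 TPM (5.14, adjusted p = 0.00371), Lox, which cross-links collagen, 0.840 and 1.30 against 50.2 and 40.7 TPM (4.49, adjusted p = 0.00367), and Serpinh1, a collagen chaperone, 0.991 and 0.905 against 10.3 and 11.4 TPM (2.60, adjusted p = 0.00619). Of genes expressed by myeloid cells, Fcer1g had 27.4 and 1.17 against 327 and 480 TPM (5.66, adjusted p = 0.0136), and Ms4a7 2.55 and 0.0728 against 24.3 and 36.1 TPM (3.97, adjusted p = 0.00793). Ms4a6c, Ms4a4c, Ly86 and Lyz2 also changed upward, by 5.49, 5.85, 2.93 and 1.53. Of the myeloid genes in this paragraph only Coro1a fell, from 7.73 and 16.8 to 0 and 0.333 TPM (-3.43, adjusted p = 0.00562). Its change was -1.22 with the GC and length correction, and it overlaps Bola2 on the other strand.

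Of the tests below, the one without the most abundant genes was set before its result was seen; the others were chosen after it.

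The excess of lower genes was weighed first. If a few abundant genes took TPM from all others, leaving them out should bring the median change near 0. Without the 179 genes that were among the 100 highest in any library, the median was -0.82, so they account for part of the shift of -1.41 and not for all of it. How large a part is uncertain, because renormalizing raises the values kept and the pseudocount of 1 then hides less of a fall. With all genes kept, the median was -1.99 with a pseudocount of 0.1 and -0.72 with 5. Against GC content or transcript length as the whole cause, the highest median among 10 bins of each was -0.80. Medians ran from -1.74 to -0.98 over the GC bins and from -2.23 to -0.80 over the length bins. The bins keep the shift from abundant genes, so GC content or length acting together with those genes was not excluded. With the GC and length correction the median was -0.07, but the correction also takes out most of each library's overall shift. For independent random loss in each library, genes at 10 TPM or more in both control libraries were counted. They were under 1 TPM in both fusion libraries 327 times. Independent loss that depends on control level alone would give 108 (odds ratio 10.3, 95% interval 8.41 to 12.6). Loss rates that differ between genes in other ways would also raise this overlap, so independent loss is not excluded. A loss that both fusion libraries share, as from 1 RNA sample or from cells in poor condition, stays open, as do genotype and sex.

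The rise of interferon response genes was weighed next. Against GC content or length as the whole cause, the list passed with the correction at a relative median of 3.97 (as deposited 3.86, with an adjusted p of 0.598 with an estimated correlation). Microglia or macrophages among the sorted cells cannot be told apart from a change within the sorted cells. How many such cells passed the gate on tdTomato was not measured. The markers summed to a mean of 91.8 TPM in the control and 215 TPM in the fusion libraries. Of 16 markers, 8 were higher in both fusion libraries after scaling and 4 as deposited, where chance gives 16.7%. Of the 12 tested markers these were 7 and 3, against 31.3% and 10.2% of all tested genes. Of the markers, Tyrobp had 105 and 116 TPM in the fusion libraries and C1qb 18.4 and 44.7, while Cx3cr1, Trem2 and P2ry12 were at 0.113 TPM or less. Genotype and sex, which differ together, stay open and untested.

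A hypothesis of this re-analysis was that imprinted genes rise as a class relative to other genes. A list of 41 was written after 7 of them had been seen, so those 7 were left out of the test. Of the 24 others tested, 1 rose, 9 fell and 14 did not pass; after median ratio scaling 5 were higher and 4 lower. Their median change of -0.92 lay at percentile 92.8 among 10000 random lists matched on mean expression, inside their middle 95% (-2.18 to -0.74). The members went both ways, so this test leaves the hypothesis undecided.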
